A study of Homo sapiens with 6 samples.

How the data were processed

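RNA was measured in A549 cells, a human lung adenocarcinoma line, of which 3 stable lines had been made with lentiviral vectors. Each line carried a short hairpin RNA under tetracycline control: a non-targeting hairpin (shNTC) or 1 of 2 hairpins against CNOT3 (shCNOT3-1 and shCNOT3-2). CNOT3 is a subunit of the CCR4-NOT complex, which shortens the poly(A) tails of mRNAs. Doxycycline (DOX), which switches the hairpin on, was given at 1 ug/ml for 72 hours, and each line was also grown without it. Per the labels' protocols, total RNA was purified with RNeasy kits, and biotinylated cRNA was made from 500 ng of it by the Affymetrix procedure. There were 6 arrays, 1 per line and DOX state.

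The deposited values were probe set intensity on a linear scale, made with MAS5 per the submitters' processing notes, whose settings are not given in the sources used here. In the deposited intensity values the mean after trimming 2% at each end was 500.1 on all arrays, the lowest value was 1, and 202 to 376 probe sets per array (0.369% to 0.688%) lay at that floor. Median intensity over all probe sets was 64.9 to 72.8. Arrays have no read depth, and their number limits the precision. The 54675 probe sets included 62 controls. In the platform annotation 42898 probe sets were listed with a gene, 41097 with 1 gene and 1801 with several, and 11777 were not listed. Symbols of 41043 of the 1-gene probe sets were updated through the Entrez identifier to current RefSeq symbols. No genome build was named, so no coordinates are given.

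Intensities were taken to log2 after adding 1, which shrinks fold changes of the dimmest genes but leaves those of dim genes uncertain. A gene was represented by its brightest 1-gene probe set, controls left out. Of 19775 genes, the 7145 whose mean log2 lay under the median of all probe sets (5.96, an intensity of 61.4) were called too dim and left out, and 12630 were tested. Tests used limma 3.58.1 in R 4.3.3 with intensity-dependent prior variance, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The main model had the stable line as a block and 1 term for knockdown, set in the 2 shCNOT3 arrays with DOX. Pairing within lines comes from the labels, because each line was grown with and without DOX. The knockdown term is the mean DOX change of the 2 shCNOT3 lines. Its 2 residual degrees of freedom hold the DOX change of the shNTC line and the difference between the hairpins. A second model with a DOX term tested the change beyond that of the shNTC line, with 1 residual degree of freedom. The prior had a median of 7.59 degrees of freedom in the first and 8.42 in the second. The hairpins were the replicates of knockdown (n = 2), with 1 array each, and nothing in the labels describes repeat cultures, so p-values measure only the spread between these arrays.

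Genes at least 2-fold different in the same direction in both shCNOT3 lines were also counted, with the shNTC change in that direction under 0.5 of the smaller hairpin change. In all, 27 gene lists were tested with camera in limma at a preset correlation of 0.01, and again with an estimated correlation and with fry, and the results of 1 of these lists are not reported here. Each list's median was also ranked among 10000 random lists matched on mean expression in 20 bins. The groups, designs, lists, naming rule and most alternatives were set before the data were examined. The naming rule took CNOT3, the other CCR4-NOT subunits and the negative cell cycle regulators. It added the 12 highest and 12 lowest called genes by the smaller hairpin change, up to 4 members per list, the 5 genes most different in each direction in the shNTC line, and 5 with opposite changes in the hairpins.

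The procedure was tested on simulated data with 12630 genes, 200 of them changed, in 5 runs. For the knockdown term, 62.8% of 2-fold and 90.8% of 4-fold changes were recovered, and 8.31% of calls were false, above the nominal rate. For the change beyond shNTC, 11.0% and 64.8% were recovered and 8.41% of calls were false. A list shifted by 0.5 on the log2 scale was called in 5 of 5 runs with either model, and other lists were called 0.2 and 0 times per run. Simulated genes were drawn independently of each other, so these list rates do not carry over to lists with correlated members. In the data the estimated correlation was, for example, 0.22 for DNA replication genes. The fold rule kept 92.6% of the 4-fold changes and took in 25.8 unchanged genes per run. Alternatives covered the scaling of the arrays, the added constant, the filter on dim genes, the choice of probe set, the variance prior, the block and each line left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.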

Results

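Gene expression was measured in 3 stable A549 lines with a DOX-inducible hairpin, each grown with and without DOX for 72 hours. The series set each line with DOX against the same line without it, so that knockdown of CNOT3 by 2 separate hairpins could be compared with a non-targeting hairpin. Between arrays, log2 intensities of the tested genes correlated at 0.954 to 0.983. The ratio of 3' to 5' probe sets, a measure of RNA integrity, was 0.966 to 1.09 for GAPDH. For ACTB it was 1.58 without and 1.47 with DOX in shNTC, 1.33 and 1.42 in shCNOT3-1, and 1.36 and 1.45 in shCNOT3-2, so it was lower with DOX in the control line and higher in both knockdown lines.

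CNOT3 itself was lower with DOX in both shCNOT3 lines. Its intensity was 227 without and 81.9 with DOX in shCNOT3-1, which left 36.4%, and 228 and 46.9 in shCNOT3-2, which left 20.9%. In shNTC it was 178 and 166, or 93.4% left. The mean log2 change of the hairpins was -1.86 ± 0.57 (SD, n = 2), and the adjusted p in limma was 0.0677, which did not pass the threshold. A second CNOT3 probe set gave log2 changes of -2.13 and -2.22 in the shCNOT3 lines but also -1.43 in shNTC, from an intensity of 259 to 95.6. A further probe set, too dim for the tests, gave -1.40 and -2.65, against 0.73 in shNTC.

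**Figure D1:**
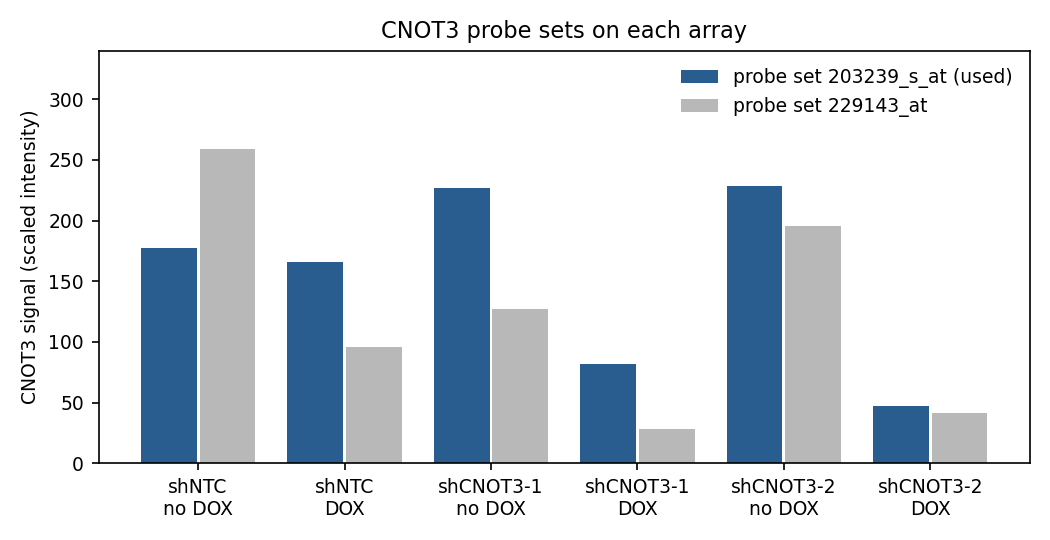
Bars show the intensity (linear scale from 0) of 2 CNOT3 probe sets on each of the 6 arrays, 1 array per bar. For the probe set used both shCNOT3 lines with DOX lay at 81.9 and 46.9, below the other 4 arrays, while the other probe set was also lower in shNTC with DOX.

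Among the genes that passed the threshold, those that rose most with CNOT3 knockdown were MARCHF4, which encodes a membrane-bound ubiquitin ligase, C6orf15 and CYP3A4, a drug-metabolizing cytochrome P450. MARCHF4 rose by 3.11 ± 0.40 on the log2 scale (SE of the model, adjusted p = 0.0230), C6orf15 by 2.69 ± 0.36 (adjusted p = 0.0230) and CYP3A4 by 2.53 ± 0.39 (adjusted p = 0.0416). The SE here and below comes from the residual and the prior of the model, not from the 2 hairpins alone. Between the hairpins (n = 2) the SD was 0.11 for MARCHF4, 0.40 for C6orf15 and 0.78 for CYP3A4. The size of these changes is uncertain, since intensities without DOX in shCNOT3-1 and shCNOT3-2 were low, at 31.5 and 85.7 for MARCHF4, 39.7 and 40.7 for CYP3A4, and under the filter level of 61.4 in both for C6orf15, down to 25.7 in shCNOT3-2. With DOX they were 295 and 704 for MARCHF4, 345 and 163 for CYP3A4 and 287 and 209 for C6orf15. In shNTC without DOX, C6orf15 and CYP3A4 already read 206 and 204, within or near the range of the shCNOT3 lines with DOX. Brighter in absolute terms was DUSP5, a nuclear phosphatase that inactivates ERK, at 2398 without and 9451 with DOX in shCNOT3-1 and 1841 and 11424 in shCNOT3-2. It rose 4.94-fold (2.31 ± 0.22, adjusted p = 0.0103), against a log2 change of -0.47 in shNTC. Among genes that fell, AQP3, a water and glycerol channel, fell by 2.13 on the log2 scale (SE 0.20, adjusted p = 0.0103), and MIGA1, a mitochondrial outer membrane protein, fell by 2.09 (SE 0.22, adjusted p = 0.0147).

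Other genes that rose were of several kinds. FGFBP1, a carrier of fibroblast growth factors, rose 3.88-fold, and PLAU, the urokinase-type plasminogen activator, rose by 1.66 on the log2 scale, where shNTC gave 0.72. GPRC5A, an orphan receptor induced by retinoic acid, rose by 1.41 from intensities of 6739 and 5358 without DOX in shCNOT3-1 and shCNOT3-2. TMC5 rose by 1.49, and MICB, a ligand of the natural killer cell receptor NKG2D, by 1.37. Smooth muscle actin ACTA2 rose by 1.61 and 1.38 in the hairpins, the long non-coding RNA LINC01588 by 1.67 and NPC1, which exports cholesterol from lysosomes, by 1.25. Adjusted p for these 8 ran from 0.0147 for GPRC5A to 0.0416 for MICB.

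Several regulators of transcription and signalling fell. LATS1, a kinase of the Hippo pathway, fell by 1.80 (adjusted p = 0.0210), REST, a repressor of neuronal genes, by 1.69 (0.0230), and ZBTB41 by 1.66 (0.0210), with -1.66 in each hairpin. SPOPL, a substrate adaptor of cullin ubiquitin ligases, fell by 1.46 and DR1, a repressor of transcription by RNA polymerase II, by 1.36. ST8SIA4, which adds polysialic acid, fell by 1.70, and the bicarbonate transporter SLC4A4 by 1.68, where shNTC gave 0.64. The secreted proteins DEFB1, a beta-defensin, and APOH fell by 1.63 and 1.37, and the chaperone DNAJC22 by 1.33. In shNTC, log2 changes of these 10 genes lay between -0.25 (DEFB1) and 0.64.

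**Figure D2:**
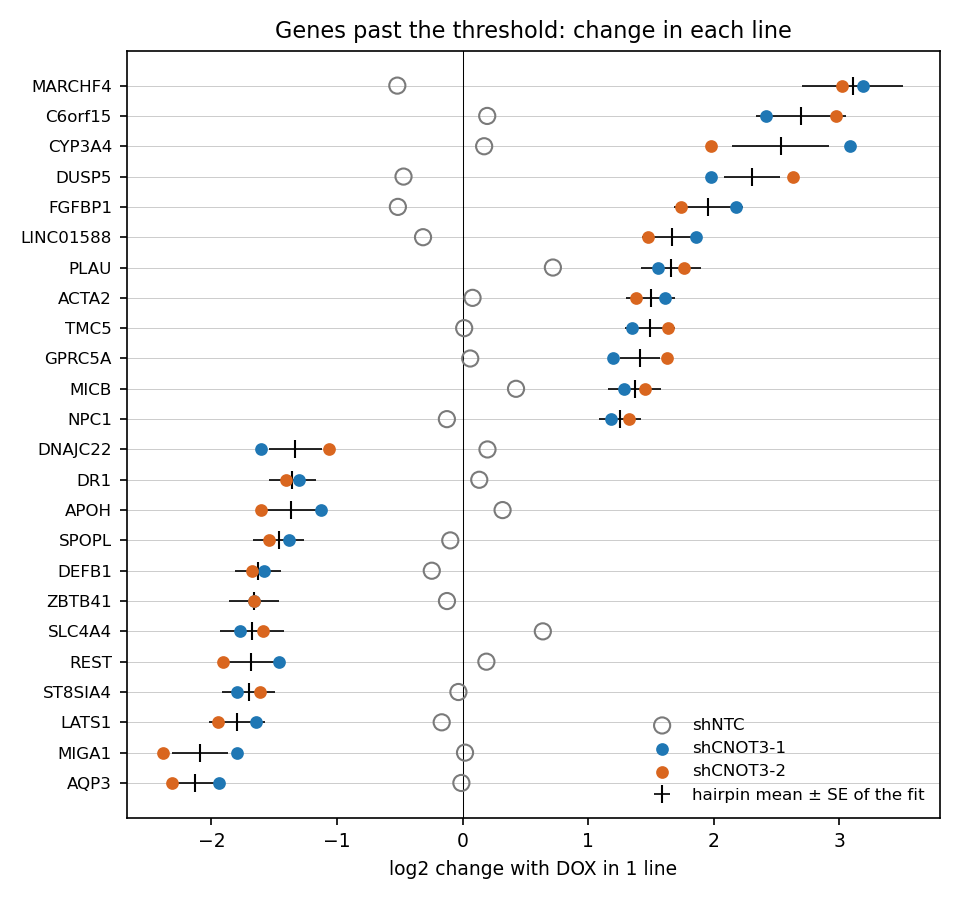
Points show the log2 DOX change of the 24 named called genes in each line (hollow grey, shNTC), and black ticks the mean of the hairpins with the standard error of the model. Both hairpins lie on the same side of 0 for each gene, from 3.11 for MARCHF4 to -2.13 for AQP3 in the mean.

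In all, 28 genes passed the threshold in limma, 13 higher and 15 lower, and in all 28 both hairpins had the same direction. At an unadjusted p under 0.05 there were 1835, of which 941 were higher. Outside the 24 above stood ID3 (1.17), AGR2 (-0.99), RAP1A (-1.29) and OIP5-AS1 (-1.42), named after their values were seen. The next 9 genes shared an adjusted p just above the threshold, and 181 genes lay under 0.1. With no block for line 191 genes passed, without shCNOT3-2 62, without shNTC 57 and without an intensity trend in the variance 0. The ACTB 3' to 5' ratio moved with knockdown too, at 1.42 and 1.45 with DOX against 1.33 and 1.36 without.

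Probe sets of 1 gene did not always move together. For DR1, 3 other probe sets gave 0.11 to 0.20 and 3 more -0.57, -0.85 and -0.92, for NPC1 another gave -0.07, for CYP3A4 0.50 and for AQP3 -1.05 and -0.20. Values were smaller in size for other probe sets of GPRC5A (1.32 and 0.42), SLC4A4 (-0.50 and -0.44) and ST8SIA4 (-0.44, -0.85 and -1.27). For REST, MIGA1 and PLAU the second probe set gave -0.97, -1.88 and 1.43. With the mean of a gene's probe sets 9 of the 24 named genes passed, and AQP3 (adjusted p = 0.0974), REST (0.151), PLAU (0.0960), CYP3A4 (0.185), NPC1 (0.252), DR1 (0.389), SLC4A4 (-0.87, adjusted p = 0.275) and ST8SIA4 (-1.07, adjusted p = 0.117) did not. Nor did FGFBP1 (0.0659), TMC5 (0.0748), DNAJC22 (0.0822), MICB and APOH (both 0.0894), GPRC5A (0.0974) and SPOPL (0.0996). For FGFBP1, MICB and APOH the mean left the log2 values unchanged, so their calls did not end because their own probe sets disagreed. After quantile normalization CYP3A4, MICB and APOH (all 0.0508) and DNAJC22 (0.0539) did not pass, though their log2 values hardly moved (2.53, 1.36, -1.36 and -1.31). Without shCNOT3-1 the calls of 14 of the 24 ended, at adjusted p from 0.0556 (TMC5) to 0.182 (DNAJC22), and without shCNOT3-2 those of 11, from 0.0507 (LATS1) to 0.120 (APOH). MARCHF4, PLAU, TMC5, MICB, NPC1, SLC4A4, SPOPL and DR1 lost the call either way, though their log2 values stayed of similar size. Without shCNOT3-1 and without shCNOT3-2 they were, for example, 3.02 and 3.19 for MARCHF4, 1.33 and 1.18 for NPC1 and -1.41 and -1.30 for DR1. With a shCNOT3 line left out knockdown is 1 pair of arrays and the residual is the DOX change of shNTC alone, so a call that remains there does not show that the hairpins match. With no block for line C6orf15 (0.356) and CYP3A4 (0.363) did not pass, and without shNTC CYP3A4 did not (0.0531).

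The hairpins were next compared without a test. Both gave at least a 2-fold difference in the same direction, beyond that of shNTC, for 136 genes, 82 higher and 54 lower, of which 26 were among the called genes. With shCNOT3-1 in the place of shNTC the count was 32, with shCNOT3-2 in its place 21, and 36 genes differed at least 2-fold in opposite directions, among them GALNT5 (-2.23 and 2.33), ZNF527 (-1.79 and 2.01), OLFM2 (-1.83 and 1.75), C19orf47 (-1.60 and 2.22) and CLDN19 (1.59 and -2.09). Across the 12630 genes, which are not independent replicates, log2 changes of the hairpins correlated at r = 0.261 (95% interval 0.244 to 0.277, Spearman 0.275). Against shNTC, r was -0.0297 for shCNOT3-1 and -0.0158 for shCNOT3-2. With no filter on dim genes r was 0.0851.

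**Figure D3:**
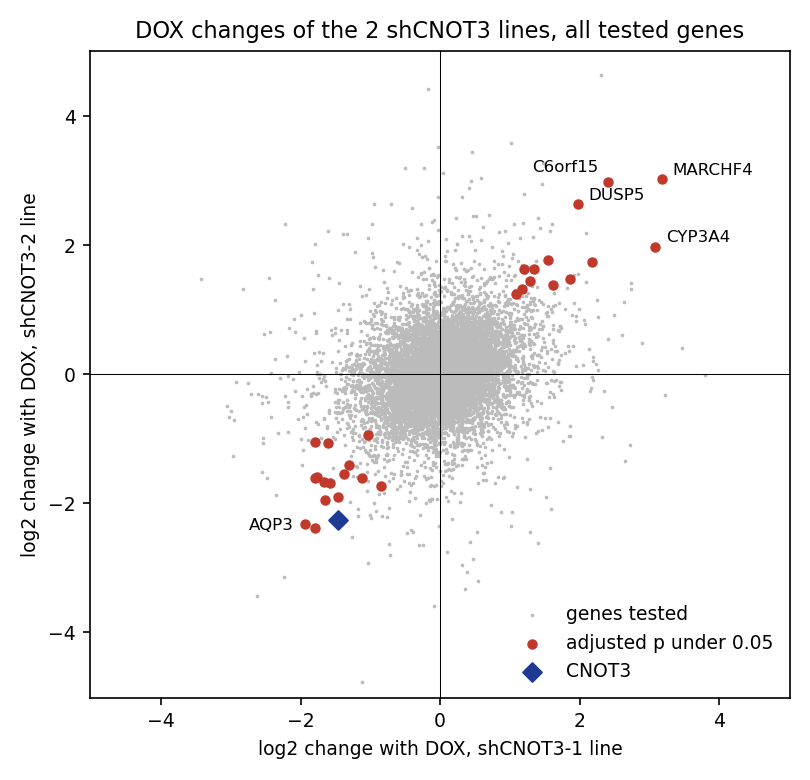
Each point is a tested gene, with its log2 DOX change in shCNOT3-1 on the horizontal and in shCNOT3-2 on the vertical axis (grey, all 12630; red, the 28 called; blue diamond, CNOT3). Called genes lie in the quadrants where both hairpins have the same sign, and r over all genes was 0.261.

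Negative regulators of the cell cycle, mRNAs that have been linked to CCR4-NOT, split in both directions. Of 18 measured members none passed over all genes tested in limma, and 3 higher and 3 lower had an unadjusted p under 0.05. Adjusted over the list alone, 3 were higher and 3 lower. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was higher in both hairpins (log2 1.14 ± 0.20, SE, adjusted p = 0.0534 over all genes, -0.10 in shNTC), as were GADD45A (0.75 ± 0.20, or 0.46 and 1.04 by hairpin) and CCNG2 (0.77 ± 0.26). CDKN2D (-1.39 ± 0.41, or -1.94 and -0.84), RBL1 (-0.66 ± 0.22, with 0.21 from another probe set) and BTG3 (-0.60 ± 0.20, or -0.27 and -0.94) were lower. In shNTC, log2 changes were -0.09 for GADD45A, -0.69 for CCNG2, 0.36 for CDKN2D, -0.36 for RBL1 and -0.16 for BTG3. Other CCNG2 probe sets gave means of 0.52, 0.20 (-0.07 in shCNOT3-2) and 0.57. For 6 others the hairpins had opposite signs: RPRM (1.35 and -0.15), BTG1 (0.83 and -0.19), CDKN2A (0.83 and -1.59), WEE1 (-0.74 and 0.28), TOB1 (0.16 and -0.42) and GADD45B (0.03 and -0.75). CDKN2A was read from a probe set of the kind that can bind several transcripts, which gave -1.06 in shNTC, so its values are uncertain. CDKN1C (-1.78 and -0.31, and -0.51 in shNTC) and CCNG1 (0.62 and 0.04, and -0.01 in shNTC) differed in size between the hairpins. For CDKN1C this depended on the probe set, since others gave -0.09 and -2.01, and -0.54 and -0.70. Means of the rest were 0.08 for CDKN1B, -0.04 for RB1, -0.23 for TOB2 and -0.40 for RBL2. In shNTC these gave 0.56, -0.33, 0.05 and -0.30. CDKN2B and GADD45G were too dim. As a group the list was not called (camera adjusted p = 0.577).

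None of the other CCR4-NOT subunits passed in limma, or had an unadjusted p under 0.05. For the 10 measured, mean log2 changes ran from -0.11 (CNOT8) to 0.47 (CNOT6L, 0.12 and 0.82 by hairpin), but other probe sets gave 0.24 and 0.26 for CNOT8 and -0.27 and -0.23 for CNOT6L. CNOT1, the scaffold of the complex, gave -0.06 and CNOT7, a catalytic deadenylase, -0.02. CNOT2, CNOT4, CNOT6, CNOT9, CNOT10 and CNOT11 gave 0.14, 0.26, -0.07, -0.09, 0.07 and 0.13, and for CNOT7, CNOT10 and CNOT11 the hairpins had opposite signs (0.52 and -0.26 for CNOT11). Adjusted over the list alone none passed either, and the list was not called (camera adjusted p = 0.694). Of 24 other decay factors 0 passed over all genes (1 higher and 3 lower unadjusted) and 1 adjusted over the list alone, the decapping enzyme DCP2 (-1.13 ± 0.20, adjusted p = 0.0543 over all genes, with -0.94 and 0.14 from other probe sets), and the list was not called (0.418). By hairpin PUM2 gave -1.24 and -0.25, where shNTC gave -0.23, ZFP36L2 -0.26 and -0.77 (a mean of -0.02 from another probe set), and TNRC6C -0.64 and -0.22.

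Of the pro-apoptotic genes 8 of 13 were higher in both hairpins, led by BIK (1.76 ± 0.30) and BAX (1.07 ± 0.20), the 2 genes that passed adjusted over the list alone. HRK gave 0.24 and 0.87 by hairpin and TNFRSF10B a mean of 0.33. In shNTC, BIK gave 0.04, BAX -0.24, HRK -0.11 and TNFRSF10B 0.30. Other TNFRSF10B probe sets gave 0.73 in shNTC, above their hairpin means of 0.51 and 0.60. Medians of the list were 0.19 and 0.36 in the hairpins and 0.04 in shNTC. The difference of the list from shNTC was not called in camera with the preset correlation (adjusted p = 0.388). That list had a camera adjusted p = 0.0128, and adjusted p = 0.533 with an estimated correlation.

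Immediate early genes, which respond within minutes to growth signals, had medians of 0.28 and 0.98 in the hairpins and 0.16 in shNTC. Among 19 measured, 6 were higher adjusted over the list alone and 1, DUSP5, over all genes. NR4A1 gave 1.16, KLF2 1.20 and CCN1 0.90 and 1.84 by hairpin, the last also 1.58 in shNTC. The camera adjusted p was 2.34e-05, and adjusted p = 0.533 with an estimated correlation. NF-kB targets and cytokines had medians of 0.30, 0.49 and -0.06, with 4 of 19 higher adjusted over the list alone. CCL20, a chemokine, read 246 without and 1225 with DOX in shCNOT3-1 and 192 and 4809 in shCNOT3-2, while in shNTC it read 189 and 18.7. IL6 gave 1.65 ± 0.45, SOD2 0.81 and RELB 0.78. Camera gave an adjusted p = 0.0167 for this list, and adjusted p = 0.577 with an estimated correlation.

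Several metabolic and stress lists also had a higher rank. Genes of the ATF4 and amino acid response had medians of 0.19 and 0.27 against -0.25 in shNTC, and 8 of 28 were higher adjusted over the list alone. They included CTH, an enzyme of cysteine synthesis (1.26 ± 0.20, SE), CHAC1 (1.26), the secreted factor GDF15 (0.93) and SESN2 (1.09). Camera gave adjusted p = 0.00530, and adjusted p = 0.631 with an estimated correlation. For lysosome and autophagy genes the medians were 0.42, 0.22 and -0.12, with NPC1 as the only 1 of 20 called in either way and CTSL at 0.54 (0.00508, and adjusted p = 0.533 with an estimated correlation). Glycolysis and hypoxia genes gave medians of 0.13 and 0.22, and 0.15 in shNTC, with 3 of 27 higher adjusted over the list alone, among them ALDOC (1.43) and ANKRD37 (1.07), where camera gave 0.00584 and adjusted p = 0.631 with an estimated correlation. Cholesterol synthesis genes gave 0.46 and 0.09, and 0.19 in shNTC, with DHCR7 (0.91, and 0.28 from another probe set) the 1 of 19 higher adjusted over the list alone and MVD at 1.70, against 2.18 in shNTC (0.0211, and adjusted p = 0.631 with an estimated correlation). Subunits of the mitochondrial ribosome were higher in both hairpins for 25 of 43, with medians of 0.14 and 0.17 against -0.14 in shNTC. None of these 43 passed in limma over all genes or adjusted over the list alone, 4 being higher unadjusted, and camera gave 0.00865, with adjusted p = 0.631 with an estimated correlation.

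Genes of DNA replication were lower in both hairpins for 27 of 40 measured members. Medians were -0.34 and -0.26, and that of shNTC was -0.17, so the control line was lower with DOX too. Adjusted over the list alone, 0 were higher and 2 lower: CCNE2, a cyclin of entry into S phase (-1.06 ± 0.22), and the flap endonuclease FEN1 (-0.96 ± 0.17, adjusted p = 0.0534 over all genes, with -0.32 from another probe set). MCM3 and GINS1 both gave -0.62. The list had a camera adjusted p = 4.56e-07, and adjusted p = 0.577 with an estimated correlation. Mitosis genes had medians of -0.11 and -0.10, and -0.17 in shNTC, with 17 of 38 lower in both hairpins. BIRC5 (-0.65, with -1.03 to 0.22 from other probe sets), KIF11 (-0.63), CDK1 (-0.51) and TOP2A (-0.49) led, and none of the 38 passed in limma over all genes or adjusted over the list alone, with 1 higher and 6 lower unadjusted. Camera gave an adjusted p = 0.0214 for mitosis, and adjusted p = 0.654 with an estimated correlation.

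Genes of the unfolded protein response were lower in both hairpins for 13 of 17, with medians of -0.28 and -0.23 against 0.05 in shNTC. XBP1, a transcription factor of that response (-1.05 ± 0.21), and SEC61B (-0.49) were lower adjusted over the list alone, and the chaperone HSP90B1 gave -0.49 (-0.21 from another probe set) and PDIA4 -0.33. The camera adjusted p was 0.00175, and adjusted p = 0.533 with an estimated correlation. Zinc finger genes with a ZNF symbol, most of them transcription factors, were lower in both hairpins for 136 and higher in both for 46 of 297 measured, 128 more being too dim. Medians were -0.10, -0.24 and, in shNTC, 0.05. No single ZNF gene passed in limma over all genes or adjusted over the list alone (7 higher and 46 lower unadjusted), and ZNF107 (-1.16, with 1.17 from another probe set), ZNF670 (-1.12), ZNF605 (-1.05) and ZNF551 (-0.97) led. Camera gave adjusted p = 2.34e-05 for the ZNF genes, and adjusted p = 0.533 with an estimated correlation. Nuclear-encoded respiratory chain genes had medians of 0.00 in shCNOT3-1 and -0.19 in shCNOT3-2, with NDUFB1 at -0.43 (-0.09 from another probe set) and COX7B at -0.29. None of 43 passed in limma over all genes or adjusted over the list alone, 2 being lower unadjusted (camera 0.0266, and adjusted p = 0.672 with an estimated correlation).

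**Figure D4:**
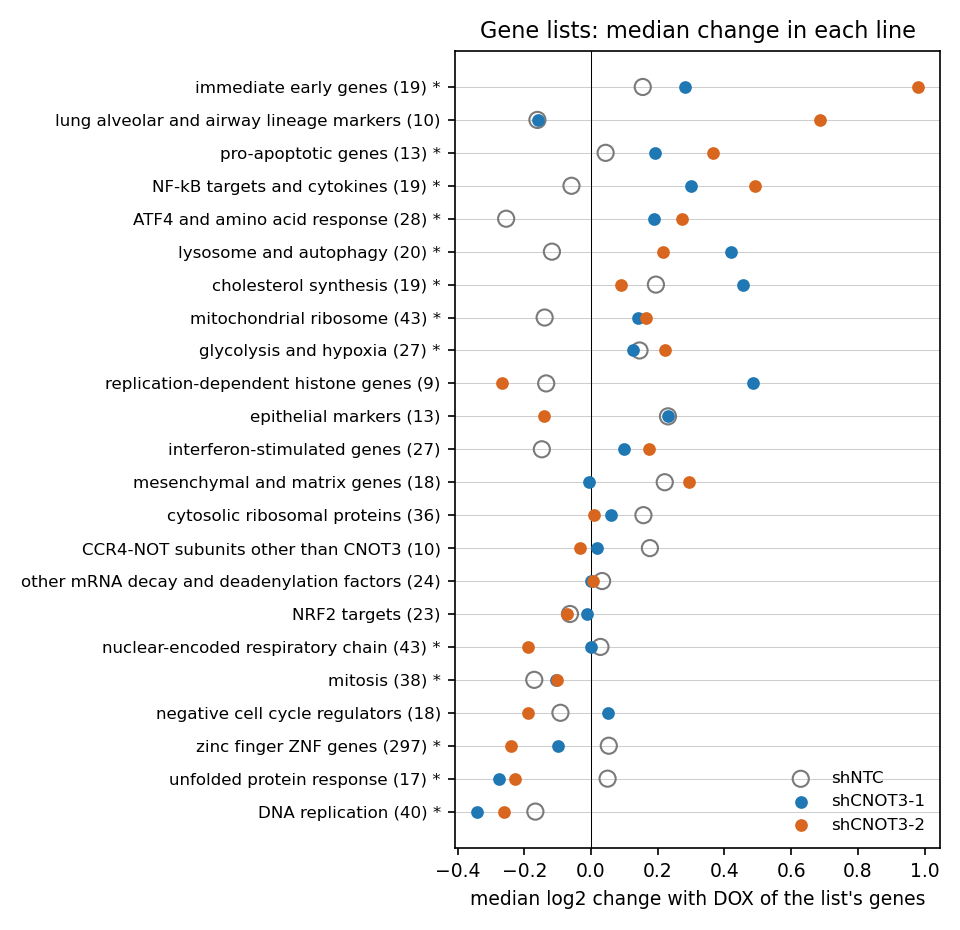
Points show each list's median log2 DOX change per line for the reported lists with at least 9 measured genes (number in brackets), and a star marks an adjusted p under 0.05 in camera with the preset correlation. Immediate early genes lie at 0.28 and 0.98 in the hairpins and 0.16 in shNTC, while DNA replication genes lie below 0 in all 3 lines.

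Camera thus called 14 lists with the preset correlation, 9 higher and 5 lower, 0 with an estimated correlation (1 at an unadjusted p under 0.05), and fry called 0. Without shCNOT3-2, where the residual comes from shNTC alone, the calls of 8 lists ended: immediate early genes (adjusted p = 0.0717), NF-kB targets (0.254), ATF4 (0.148), pro-apoptotic genes (0.131), glycolysis (0.148), mitosis (0.199), respiratory chain (0.838) and mitochondrial ribosome (0.0837). Without shCNOT3-1 those of cholesterol synthesis (0.261) and lysosome genes (0.129) ended, and with no block for line those of mitosis (0.338) and cholesterol synthesis (0.121). The ACTB ratio, higher with DOX in both shCNOT3 lines, moved along with these lists there. The GAPDH ratio, higher with DOX in shCNOT3-1 and lower in shCNOT3-2, did not. In shNTC the ACTB ratio was lower with DOX and did not follow all of the lists. There the median had the same sign as in the hairpins for lists such as DNA replication (-0.17), mitosis (-0.17) and immediate early genes (0.16). It had the opposite sign for others, such as ATF4 (-0.25).

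The other lists were not called. Interferon-stimulated genes, which can respond to double-stranded RNA, had a mean-change median of 0.10 over 27 genes (camera adjusted p = 0.418), with GBP1 at 1.26 but also 1.23 in shNTC and IFIT3 at 0.58. Cytosolic ribosomal proteins gave 0.03 (36 genes, 0.577), NRF2 targets -0.04 (23 genes, 0.145, with UGDH, at -1.15 and -0.44 by hairpin, lower adjusted over the list alone), epithelial markers 0.10 (13 genes, 0.386, KRT19 1.13 and 0.45 by hairpin), mesenchymal and matrix genes 0.10 (18 genes, 0.475, SPARC 0.87) and histone genes 0.11 (9 genes, 0.830, H2BC4 0.92 and 0.12 by hairpin). The histone list split by hairpin, with medians of 0.49 in shCNOT3-1 and -0.27 in shCNOT3-2. In fits with 1 shCNOT3 line, whose residual is the DOX change of shNTC alone, adjusted p was 0.0274 for this list without shCNOT3-2 and 0.0442 without shCNOT3-1, and 0.0342 for NRF2 targets without shCNOT3-1, which are not taken as calls. Among 10 lung lineage markers, FOXA2, a transcription factor of airway and liver (-1.05 ± 0.19), and the mucin MUC5B (-1.47 ± 0.40) were lower adjusted over the list alone. For MUC5B the mean rests mostly on shCNOT3-2, at -2.46 against -0.48 in shCNOT3-1. The list's median was 0.28 while camera's direction was down (0.830). Markers of cells not meant to be in the cultures were mostly too dim: 3 of 12 fibroblast markers were measured (median 0.27, adjusted p = 0.530), 4 of 12 on the array for leukocytes (0.34, 0.531) and 2 of 10 for endothelium (0.34, 0.472), where PECAM1 (0.79) passed adjusted over the list alone.

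The change beyond that of the control line was tested last. No gene passed in limma, and 1061 lay at an unadjusted p under 0.05 (566 higher and 495 lower). CCL20 was nearest to the threshold of the genes named here, with a log2 difference of 6.74 ± 0.79 (adjusted p = 0.0907) that rests in part on its low intensity of 18.7 in shNTC with DOX. DUSP5 followed with 2.78 ± 0.36 (adjusted p = 0.0944), and CNOT3 gave -1.76 (0.530). FGB, named after its values were seen, gave -3.17 (adjusted p = 0.0973), since this fibrinogen chain read 1178 without and 3411 with DOX in shNTC but 641 and 261 in shCNOT3-1 and 713 and 180 in shCNOT3-2. With each array centred on its median 7 genes passed, and with 32 added before the log 4 did.

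In the control line, DOX went with at least 2-fold differences for 507 genes (230 higher and 277 lower), without a replicate. In shCNOT3-1 and shCNOT3-2 the counts were 866 (432 and 434) and 816 (454 and 362). In shNTC, PHKG2 (3.32), H4C9 (2.92), TNFSF13 (2.91), RASAL1 (2.77) and SLC37A1 (2.74) were the highest and CHST2 (-4.31), TRABD (-3.93), HAAO (-3.77), DNAH6 (-3.28) and CCL20 (-3.27) the lowest. PHKG2 read 14.3 without and 152 with DOX, and CHST2 109 and 4.53, so these rest on low intensities. For TRABD the other probe sets gave only -0.17 and -0.18 in shNTC. The standard deviation of log2 changes over all tested genes was 0.47 in shNTC, 0.55 in shCNOT3-1 and 0.55 in shCNOT3-2.

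Without DOX the lines also differed. At least 2-fold differences were seen for 362 genes between shCNOT3-1 and shNTC (174 higher and 188 lower), 405 between shCNOT3-2 and shNTC (140 and 265) and 378 between shCNOT3-2 and shCNOT3-1 (137 and 241), with 1 array each. After quantile normalization the last 2 comparisons split as 170 and 207 and as 167 and 185, and after median centring 365 genes differed between shCNOT3-1 and shNTC, 192 higher and 173 lower. For CNOT3 the probe sets differed: the one used read 227 and 228 in the shCNOT3 lines and 178 in shNTC, while the second read 127 and 195 against 259.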

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

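Of the tests in this part, the doxycycline tests and the count of unlisted probe sets were chosen after the results were seen, while the other ZNF tests and the exchange of line roles were set before their own values were examined. For 10 lists, 9 of them given here, the change in the shCNOT3 lines differed from that in shNTC, in camera on the difference with the preset correlation, and none did with an estimated correlation.

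Median log2 differences from shNTC were 0.42 for the ATF4 list (adjusted p = 3.06e-05), 0.66 for NF-kB targets (0.00328), 0.32 for lysosome genes (0.00140), 0.28 for the mitochondrial ribosome (7.58e-04) and 0.23 for immediate early genes (0.0176). They were -0.23 for ZNF genes (7.58e-04), -0.27 for the unfolded protein response (0.00276), -0.11 for cytosolic ribosomal proteins (0.00314) and -0.083 for the respiratory chain (0.0156). The lowest adjusted p for any list was 0.780 with an estimated correlation, and the difference rests on a single shNTC pair.

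ZNF genes, lower in both hairpins, were the first pattern weighed. Probe sets that can bind several transcripts are argued against as the source, because with them left out the median over 246 genes was -0.18, as with all probe sets. Level alone is argued against too, as both the 148 brighter genes (median -0.17) and the 149 dimmer ones (-0.23) lay at percentile 0 of matched lists. In shNTC the median was at percentile 99.1, but 1 pair cannot exclude doxycycline. The cause stays open.

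DNA replication genes were the second. Their shNTC median of -0.17 lay at percentile 0.16 of matched lists, so doxycycline alone could account for part of the lower values in the shCNOT3 lines. The difference from shNTC was -0.09 in the median and was not called (adjusted p = 0.358). Knockdown as a further contribution stays open and was not separable here.

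Whether chance alone gives 28 called genes was asked by giving the knockdown role to other lines or turning 1 line. The real assignment gave 28, the highest of the others 0, and 1 of 6 assignments reached the real count, too few for a share under 0.05. Each other assignment also puts a change shared by the hairpins into the residual, so its count does not show what chance gives. Outside the main measurement, 35 of 2997 probe sets above the filter with no listed gene were at least 2-fold different in both hairpins, 16 higher and 19 lower. With shCNOT3-1 or shCNOT3-2 in the role of shNTC the count was 19 each time. The share, 1.17%, compares with 1.08% of tested genes, and r between the hairpins was 0.170.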

How the results depend on the processing

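The alternatives with a filter at an intensity of 200 and all those for the differences between lines without DOX were chosen after seeing the data. So was the fit of the ZNF list without probe sets that can bind several transcripts. For the 28 called genes, no block for line gave 191 (25 of the 28 shared), a constant of 32 54, no filter 3, the mean of probe sets 9, no variance trend 0, and a filter at 200 51. Leaving out a line gave 39 to 62, with 11, 14 and 27 shared without shCNOT3-1, shCNOT3-2 and shNTC, and without a shCNOT3 line the residual comes from shNTC alone. Of the 24 named, 20 passed with quantile normalization, 9 with the mean of probe sets and 10 to 23 with a line left out. The change beyond shNTC gave 7 genes with median centring and 4 with 32 added, and the fit with a line left out was not run, since no residual degrees of freedom or no control would remain. The 2-fold count of 136 was 606 at 1.5-fold, 17 at 3-fold, 76 with 32 added, 679 with no filter and 64 at the filter of 200, and it needs both hairpins, so none was left out. Called lists, 14, were 0 with an estimated correlation or fry and 7 to 14 with a line left out. The r of 0.261 was 0.298 with 32 added and 0.0851 with no filter. With 32 added, shNTC gave 300 genes in place of 507, and lines without DOX differed for 181, 207 and 175. The histone list turned to -0.27 without shCNOT3-1 and ranged up to 0.49. CNOT3 stayed lower under each alternative, from -1.45 to -2.26, with adjusted p from 0.0618 to 0.495. Of 1216 alternatives for named genes, 1096 kept direction and side of the threshold, 47 lost the call and 32 gained it. Only the 24 called genes could lose it, and most of the 1096 were for genes with no call in either fit. In 41 the direction changed with no call in either fit, and in none did it change with a call. Of 271 for lists, 219 kept both, 40 lost and 2 gained the call, 9 changed direction without a call and 1 with a call. All 40 losses were among the 14 called lists. The block changed no other call than those given here and in the 20 named genes it moved, 18 into and 2 out of the threshold. The filters change the number of genes tested by construction, and the cause of the other shifts was not tested.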

Other observations

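The ERK test was chosen after part of its result had been seen, since 5 of its 20 genes, FOSL1, DUSP6, IER3, MYC and LIF, stood in lists already examined. The liver test was prompted by genes that were then left out of it, and was set before the values of its own list were examined.

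Genes of liver-type secretion, some of which A549 cells express, had lower medians with DOX in both shCNOT3 lines and a higher one in shNTC. The ACTB ratio also changed in opposite directions in the shCNOT3 lines and in shNTC, so RNA integrity as read from ACTB was not separable from knockdown here. The GAPDH ratio did not move with knockdown, being higher with DOX in shCNOT3-1 and lower in shCNOT3-2. FGB, FGG, APOH and FOXA2 had been noticed, with mean log2 changes of -1.64, -1.69, -1.37 and -1.05, and APOH alone passed the threshold in limma. Its call ended with quantile normalization (-1.36, adjusted p = 0.0508) and the mean of probe sets (-1.37, 0.0894), though its value hardly moved. With shCNOT3-2 left out the call also ended, at a log2 change of -1.125. The hypothesis that a liver-type program falls with knockdown was tested on 42 other genes, of which 22 were measured. Their medians were -0.43 and -0.52 in the hairpins and 0.26 in shNTC, and 12 were lower and 2 higher in both hairpins. Both hairpins lay at percentile 0.01 of matched random lists, and shNTC at 99.3. By hairpin SERPINA6, a carrier of steroid hormones, gave -3.06 and -0.49 and the fibrinogen chain FGA -0.74 and -2.08, so each rests mostly on 1 line. AMBP gave a mean of -1.45 but also -1.47 in shNTC. SERPINA6, AMBP, HPX, TTR and F2 were dim, with mean log2 intensities of 6.24 to 6.49 against a filter level of 5.96. Means were highest for AHSG (0.63), F12 (0.42), NR5A2 (0.35) and CEBPA (0.34), and C3 split by hairpin (1.57 and -1.45). CPS1, an enzyme of the urea cycle, gave a mean of -0.72, and 0 of the 22 passed in limma over all genes, with 0 higher and 5 lower unadjusted. Camera gave p = 0.00115 with the preset correlation and 0.112 with an estimated one. The percentiles are consistent with the hypothesis, but the call does not hold with an estimated correlation and each hairpin line has 1 pair of arrays.

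Higher DUSP5 and PLAU led to the hypothesis of higher output of the ERK pathway, tested on 20 other genes, of which 19 were measured. Their medians were 0.23 and 0.30 in the hairpins and 0.12 in shNTC, 11 were higher and 3 lower in both hairpins, and percentiles were 95.7 and 99.6, against 93.9 in shNTC. FOSL1 gave 1.30, EREG, a ligand of the EGF receptor, 0.51 and 1.92 by hairpin, EPHA2 0.92, PHLDA1 0.53 and DUSP4 0.42, while SPRED1 gave -0.16 and -0.49 by hairpin, CCND1 a mean of -0.30 and SPRED2 a mean of -0.22, almost all from shCNOT3-1 (-0.43), and none passed in limma over all genes, with 5 higher and 0 lower unadjusted. Camera gave p = 0.00437 with the preset correlation and 0.169 with an estimated one. The values may fit such a hypothesis, but shNTC lay just under the bound set for it, so the 3 lines are not clearly apart.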
